A study of Arabidopsis thaliana with 12 samples.

How the data were processed

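RNA from Arabidopsis thaliana rosette leaves was measured on 12 Affymetrix ATH1 arrays, each hybridised with biotin-labelled cRNA, per the labels. Each array stands for a pool of 40 plants, per the series description. Plants were grown in a greenhouse at 20 °C, 80% humidity and a 16 h photoperiod. The table deposited by the authors holds 1 linear intensity for each of 22810 probe sets on each array. The scaling was read from the values: after trimming 2% of probe sets at each end, the mean intensity was 100.01 on every array, so the deposited values had been brought to a common level per array. The values carry no log transform and no centring per probe set. The software that summarised the probes into 1 value, and the unit of its scale, are not given in the sources used here. The array type and its number of probe sets are those stated in the labels.

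Samples were grouped by genotype and growth stage as the sample names give them, into 4 groups of 3 arrays: Col-0 and SPH1 RNAi, each at stages 1.05 and 1.14. One array, SPH1 RNAi at stage 1.14 replicate 3, lacks the RNAi tag that the other arrays of its group carry, and it was grouped by its source name and title. The titles of SPH1 RNAi at stage 1.14 replicates 2 and 3 mark these 2 arrays as repeated hybridisations. All 12 arrays entered the analysis. Average background ranged from 68.5 to 136.5 in the labels, and the number of arrays limits the precision of every value. Between 54.0% and 59.8% of the probe sets on an array had a signal of at least 32.

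Control probe sets, 64 in all, were left out. The other 22746 were tested where their mean over the 12 arrays was at least 32, which left 13263. The values were transformed as log2 of the signal plus 16, and 1 model with 4 groups and 8 residual degrees of freedom was fitted in R 4.3.3 with limma 3.58.1 (lmFit, and eBayes with an intensity trend). From it came 6 comparisons: SPH1 RNAi against Col-0 at each stage, the average of both, stage 1.14 against 1.05 in each genotype, and the interaction of genotype and stage. Probe sets passed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are those of the signal plus 16, so for probe sets near 0 they are smaller than the ratio of the signals. The p-values measure the spread between these arrays. For single values, exact two-sided permutation tests were used, and with 3 arrays against 3 these cannot give a p below 0.1.

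Probe sets were paired with genes through the list of probe sets and loci used here. It names 14016 probe sets, 13513 of them with 1 gene and 503 with several, and leaves 8730 unnamed here. Among the tested probe sets, 7095 (53.5%) had 1 gene, 267 had several and 5901 were unnamed here. Symbols and the order of neighbouring genes were taken from the TAIR10.1 gene list. It was used for names and order alone, and no coordinates are given, since the build behind the array is not given in the sources used here. Many well-studied genes are among those without a listed probe set, so the gene lists were measured in part.

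The groups, the tests, the rule for named genes, 24 gene lists and most alternatives were chosen before the data were examined. Named genes are, per comparison and direction, the 12 with the largest change among those that passed, whose 3 arrays of one group all lay above the 3 of the other (for the average, at both stages) and whose probe set has exactly 1 gene. For the interaction they are the 10 with the smallest p. From each gene list up to 4 members are named, and SPH1 and its measured homologues in addition. Lists with at least 4 tested genes, 1 probe set per gene, were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists. Shorter lists are described by their members' values. A further 4 lists, the search for runs of neighbouring genes and the slope between the stage changes were chosen after the data had been seen.

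Runs of neighbouring genes were sought by the highest-scoring stretch of genotype differences in gene order, each difference limited to 1 on the log2 scale and lowered by 0.3. The stretch was set against 1000 shuffles of the gene order. The slope of the SPH1 RNAi stage change on the Col-0 stage change was corrected for the error of the latter. Each step was tested on simulated data. Each fit of 13263 probe sets held 100 known changes of 1 and 100 of 2 on the log2 scale. Of the changes of 1, the test found 79 at stage 1.05, 69 at stage 1.14 and 92 for the average. It found 71 for the Col-0 stage change, 62 for the SPH1 RNAi stage change and 30 for the interaction. Of the changes of 2 it found 96, 99, 100, 97, 93 and 82 in the same order. Unchanged probe sets made up 4.89%, 3.45%, 5.42%, 9.19%, 8.28% and 5.88% of all calls, those for both sizes included. These shares were above the 5% aimed at in 4 of the 6 comparisons. A planted run was found in 20 of 20 simulations, and a slope of 0.5 was estimated as 0.502.

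The alternatives were quantile normalization, 1 or 64 in place of 16 before the log2, no filter or a minimum mean of 64, the replicate number as a block, no intensity trend, array quality weights, only the 6 arrays of the groups compared, each array left out in turn, and the 2 repeated hybridisations left out. The log2 ratio of the 3′ to the 5′ actin control signal as a covariate was added after the data had been seen, as were, for the gene list tests, each array left out in turn and 1 or 64 in place of 16.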

Results

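Transcript levels were measured in rosette leaves of Arabidopsis thaliana plants carrying an RNA interference construct against SPH1, and in the Col-0 accession without it. RNA interference lowers a chosen mRNA through double-stranded RNA of the same sequence. SPH1 belongs to the S-protein homologues, small secreted proteins related to the self-incompatibility proteins of poppy stigmas. Leaves were taken at growth stages 1.05 and 1.14, on the scale that counts rosette leaves, so the 12 arrays fall into 4 groups of 3. The study asked which transcripts of the developing leaf depend on SPH1. Average background on the arrays lay between 68.5 and 136.5, and the median signal between 37.7 and 48.4 on a scale whose trimmed mean was 100.01 on each array. The number of arrays limits the precision.

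No probe set is listed for SPH1, so the level of the targeted transcript could not be checked in any array. Of 18 loci in the S-protein homologue list, 9 had a probe set, and none reached the mean signal needed for the test. Over the 12 arrays AT1G04645 had a mean of 2.88, AT2G06090 of 9.48, AT3G16970 of 4.38, AT3G17080 of 1.13, AT3G24060 of 4.59, AT3G26870 of 3.76, AT3G26880 of 7.18, AT5G06020 of 4.54 and AT5G38440 of 10.96. These means lie under the offset of 16 added before the log2, so no difference between the groups could be read from them.

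Growth stage was the main axis of difference between the arrays. The first principal component held 55.5% of the variance and separated the stages, and the second held 15.4%. SPH1 RNAi at stage 1.14 replicate 1 stood apart from its group, with a correlation across probe sets of 0.894 and 0.904 to the other 2 arrays, against 0.969 between those, and with the lowest position on the second component, -41.3. The log2 ratio of the 3′ to the 5′ actin control signal, a sign of RNA integrity, was 1.88 ± 0.43 (SD, n = 3) in Col-0 at stage 1.05 and 1.01 ± 0.08 at stage 1.14 (exact permutation p = 0.1, the smallest that 3 against 3 can give). In SPH1 RNAi it was 2.09 ± 0.81 and 1.25 ± 0.34 (exact permutation p = 0.3). Between the genotypes the exact p was 0.8 at stage 1.05 and 0.4 at stage 1.14. The same ratio for the GAPDH control was 0.20 ± 0.18 and 0.20 ± 0.03 at the 2 stages in Col-0. In SPH1 RNAi it was 0.47 ± 0.32 and 0.30 ± 0.24 (SD, n = 3, exact permutation p = 0.5), so GAPDH showed no clear change with stage. Average background at stage 1.05 was 106.89 ± 17.8 in Col-0 and 72.78 ± 5.85 in SPH1 RNAi (SD, n = 3; exact permutation p = 0.1, the smallest possible), and at stage 1.14 it was 88.35 ± 15.3 and 99.07 ± 32.8 (exact p = 0.8).

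**Figure D1:**
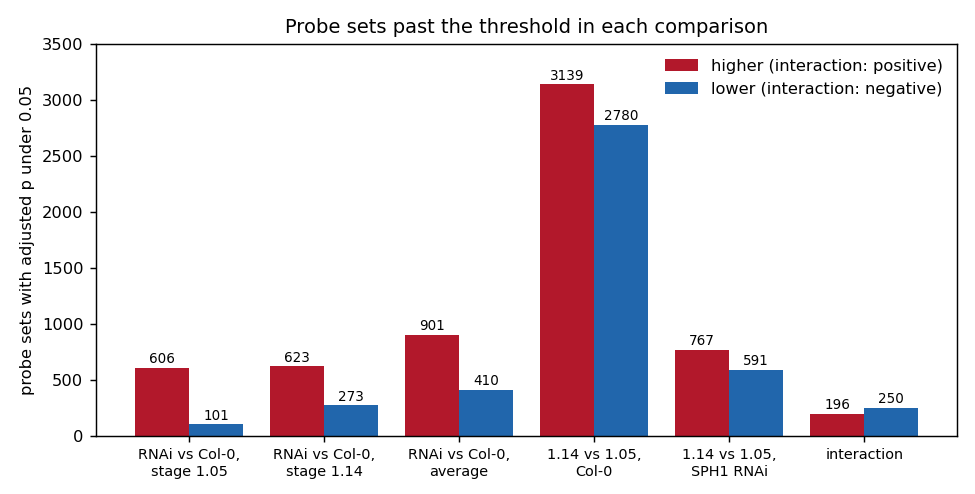
Number of probe sets past the threshold in each of the 6 comparisons, split into higher and lower (for the interaction, positive and negative). The Col-0 stage comparison holds the most, with 3139 higher and 2780 lower of 13263 tested.

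The comparison of SPH1 RNAi with Col-0 at stage 1.05 asks what the construct changed in young rosettes. Here 606 probe sets were higher and 101 lower in the RNAi plants. CHI, a putative chitinase, rose 15.0-fold, from a signal of 38.3 ± 7.3 in Col-0 to 888 ± 447 in SPH1 RNAi (SD, n = 3; limma adjusted p = 4.39e-05). AT1G13470 rose from 7.43 ± 5.15 to 205 ± 36 (log2 change 3.24 ± 0.20 SE, adjusted p = 1.24e-05), and AT2G44240 from 3.50 ± 0.90 to 657 ± 436 (4.79 ± 0.57, adjusted p = 0.000328). DFR, the dihydroflavonol reductase of anthocyanin synthesis, fell 3.46-fold, from 300.3 ± 29.1 to 75.3 ± 8.5 (adjusted p = 0.00925).

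Among the other genes with the largest rises at stage 1.05 were AT1G57630, which encodes a protein with a TIR domain as found in immune receptors (log2 change 2.99 ± 0.43 SE), and AT3G47480, a calcium-binding EF-hand protein (2.63 ± 0.19). AT5G55450 of the lipid-transfer protein family rose by 2.69 ± 0.34, the AAA-type ATPase AT3G28540 by 2.67 ± 0.32, and AT4G00700, which has C2 domains, by 2.49 ± 0.28. AT1G76960 (3.30 ± 0.33), AT5G52760 (2.81 ± 0.42), AT1G21520 (2.79 ± 0.20) and AT3G18250 (2.54 ± 0.43) completed the 12. The lower genes were led, after DFR, by SAG29, a sugar transporter of the SWEET family, at -1.74 ± 0.44. The cellulose synthase-like CSLA01 was at -1.55 ± 0.24 and AT5G62210 at -1.54 ± 0.38. The cytochrome P450 AT3G44970 was at -1.32 ± 0.16, AT3G26960 at -1.30 ± 0.30, AT1G48100 of the polygalacturonase family at -1.29 ± 0.26 and AT4G02850 at -1.29 ± 0.25. The MATE transporter AT5G44050 (-1.15 ± 0.22) and the glycosyl hydrolase GH9C2 (-0.95 ± 0.19) fell too. GH9B8, of the same hydrolase family, had 151 ± 2 in Col-0 and 68.3 ± 11.2 in SPH1 RNAi, and the thylakoid ascorbate peroxidase TAPX 542 ± 32 and 264 ± 24 (signal, SD). For these 24 genes, limma adjusted p lay between 1.24e-05 and 0.0381. By the rule for named genes, the 3 arrays of one genotype all lay above the 3 of the other. SAG29, AT5G62210, AT3G26960, AT1G48100 and GH9C2 did not pass without SPH1 RNAi at stage 1.05 replicate 2, nor without Col-0 at stage 1.05 replicate 3. Without SPH1 RNAi at stage 1.05 replicate 1 the log2 change was 5.54 in AT2G44240 and 3.18 in AT3G18250.

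By gene list, flavonoid and anthocyanin synthesis stood out at stage 1.05. Of its 4 tested genes DFR fell and 3 did not pass, while adjusted over the list alone 3 fell. Their median log2 change was -1.72 (camera adjusted p = 0.000303, and adjusted p = 0.348 with an estimated correlation). The anthocyanin glycosyltransferases AT4G14090 and UF3GT had log2 changes of -2.25 ± 0.66 and -1.65 ± 0.48 (limma adjusted p = 0.0733 and 0.0683), and UGT78D2 one of -0.84 ± 0.39 (adjusted p = 0.250). GRX480, the salicylate-induced glutaredoxin and the only tested gene of its list, rose 2.00-fold (limma adjusted p = 0.00671). In the leaf senescence list, WRKY53, a transcription factor of senescence, rose 2.23-fold (adjusted p = 0.0134), SAG29 fell, and SAG101 had a log2 change of 0.88 ± 0.25 (adjusted p = 0.0615); adjusted over the list alone, 2 rose and 1 fell. No call was made for the 5 other lists that camera tested, which were photosystem subunits, expansins and xyloglucan endotransglucosylases, cold, drought and ABA response, heat shock, and auxin response (adjusted p from 0.496 to 0.802). The cytokinin response regulators RR16 and ARR15 had log2 changes of -0.70 ± 0.21 and -0.62 ± 0.24 and did not pass, though both fell adjusted over the list alone.

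At stage 1.05, 707 of 13263 probe sets passed in limma (5.33%), 350 of them at least 2-fold, and 2658 had an unadjusted p under 0.05. The count was 365 without SPH1 RNAi at stage 1.05 replicate 2, 456 without its replicate 3, 386 without Col-0 at stage 1.05 replicate 2 and 374 without its replicate 3. It was 1753 with array quality weights.

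In the same comparison at stage 1.14, for older rosettes, 623 probe sets were higher and 273 lower in SPH1 RNAi. The plant defensin PDF1.2, a marker of jasmonate and ethylene responses, fell 14-fold, from 772 ± 536 in Col-0 to 33.3 ± 31.6 (SD, n = 3; limma adjusted p = 0.02), and its close relative PDF1.2b fell from 1255 ± 878 to 53.6 ± 58.8 (adjusted p = 0.0217). Col-0 had 176.5 on replicate 2 against 1214.1 and 925.3 for PDF1.2; without that array the log2 change of PDF1.2 was -4.63 in place of -3.80, and that of PDF1.2b -4.96 in place of -4.12 (PDF1.2b -4.77 without SPH1 RNAi at stage 1.14 replicate 1). Neither passed without Col-0 at stage 1.14 replicate 1 or 3, or without SPH1 RNAi at stage 1.14 replicate 3. COR47, a dehydrin induced by cold and drought, fell 2.64-fold, from 1320.2 ± 257 to 493 ± 112 (adjusted p = 0.00240). AT4G29030 rose 9.56-fold, from 24.6 ± 7.1 to 400.2 ± 190.3 (adjusted p = 0.000453).

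**Figure D2:**
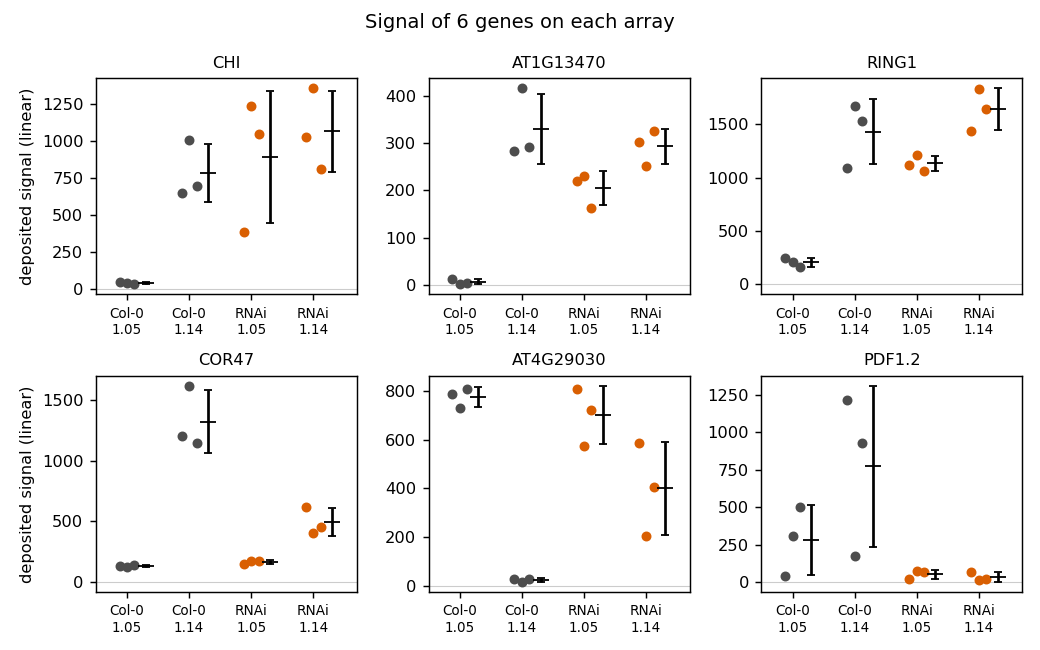
Deposited linear signal of 6 genes on each of the 12 arrays, by group, with the mean and SD of 3 arrays beside the points. In Col-0, CHI, AT1G13470 and RING1 are low at stage 1.05 and high at stage 1.14, while both SPH1 RNAi groups are high.

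Among the other genes that rose at stage 1.14, AT1G62500 and AT4G22490 of the lipid-transfer family had log2 changes of 3.28 ± 0.56 and 2.27 ± 0.50 SE, and AT5G01870, another member, 1.86 ± 0.35. The osmotin-like AT2G28790 rose by 2.65 ± 0.43, the thaumatin-like ATLP-1 by 1.81 ± 0.40, the peroxidase AT3G21770 by 2.21 ± 0.44, the GDSL-type lipase AT5G45670 by 2.02 ± 0.32 and the glycosyl hydrolase GH9B13 by 1.93 ± 0.40. The 3 SPH1 RNAi arrays differed widely in AT1G62500 (366.5 ± 390.3, SD), AT2G28790 (589 ± 529.9), AT4G22490 (253.4 ± 229.2) and AT4G10270 (253.6 ± 294.4). Without replicate 1, the array that stood apart, the log2 change was 2.48 in AT1G62500, 1.98 in AT2G28790, 1.61 in AT4G22490 and 1.45 in AT4G10270. AT3G57950 rose by 2.81 ± 0.24, AT4G10270 of the wound-responsive family by 2.33 ± 0.58 and AT4G16800 of the enoyl-CoA hydratase family by 1.83 ± 0.23. On the lower side stood the lectin-like AT3G16530 (-3.14 ± 0.41), AT1G78460 (-1.86 ± 0.21), AT1G19960 (-1.81 ± 0.48), AT5G62360, a member of the pectin methylesterase inhibitor family (-1.53 ± 0.25), and AT1G30250 (-1.52 ± 0.22). AT1G64370 (-1.43 ± 0.19), AT1G52510 (-1.42 ± 0.29), the protein phosphatase AT3G16800 (-1.37 ± 0.14) and AT1G80130 (-1.36 ± 0.33) followed. Adjusted p in limma ranged from 0.000453 to 0.0430 over these 24 genes, with no overlap between the genotypes in any of them, as the rule for named genes requires. Not all of them passed with a Col-0 array of stage 1.14 left out: AT4G22490 and AT4G10270 did not without any one of the 3, ATLP-1 and GH9B13 without replicate 2, AT3G21770 without replicate 3, and AT1G52510 without either of these. AT1G80130 did not pass without Col-0 replicate 2 or SPH1 RNAi replicates 1 or 3 of that stage, and AT1G19960 without 9 of the 12 arrays.

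Among the lists fixed beforehand, cold, drought and ABA response gave the lowest p at stage 1.14. Of 4 tested genes COR47 and the dehydrin LTI30 (-0.89 ± 0.18, limma adjusted p = 0.0168) fell, and COR15A (-1.82 ± 0.64) and COR15B (-0.98 ± 0.30) did not pass, while all 4 fell adjusted over the list alone. Their median log2 change was -1.19 (camera adjusted p = 4.07e-05, and adjusted p = 0.0841 with an estimated correlation). Flavonoid and anthocyanin synthesis had a median of -0.82 with 0 of 4 genes past the threshold, also over the list alone (camera adjusted p = 0.0425, and adjusted p = 0.489 with an estimated correlation). Photosystem and electron transport subunits had a median of -0.42 with 0 of 4 past it (camera adjusted p = 0.0313, and adjusted p = 0.489 with an estimated correlation). After quantile normalization the camera adjusted p of the flavonoid and photosystem lists was 0.0779 and 0.117, and the photosystem median -0.27. Without SPH1 RNAi at stage 1.14 replicate 1 both were at 0.117, and the photosystem median was -0.24. The flavonoid call was also lost without Col-0 at stage 1.14 replicate 2 (adjusted p = 0.378, median -0.16), SPH1 RNAi at stage 1.14 replicate 2 (0.0730) or stage 1.05 replicate 1 (0.0519), and with 64 in place of 16 (0.0578, median -0.55). The photosystem call was lost without Col-0 at stage 1.14 replicates 2 (0.0730) or 3 (0.0540). Expansins, heat shock and auxin response had camera adjusted p from 0.277 to 0.883, and auxin response had 0.0264 without SPH1 RNAi at stage 1.14 replicate 1. PRL, a subunit of the DNA replication helicase, rose by 0.82 ± 0.19 (limma adjusted p = 0.0249), and the Aurora kinases AUR1 and AUR2 had changes of 0.62 ± 0.19 and 0.68 ± 0.20 and did not pass; all 3 rose adjusted over the list alone. Of the light harvesting proteins LHCB4.2 fell by 0.61 (limma adjusted p = 0.0324), and LHCB4.3 (-1.09) and LHCB4.1 (-0.26) did not pass; adjusted over the list alone 2 fell. RR16 fell by 0.99 (limma adjusted p = 0.0173). The root marker PYK10, a beta-glucosidase, had a signal of 355 on SPH1 RNAi at stage 1.14 replicate 1, 39.4 and 61.3 on replicates 2 and 3, and 17.3 ± 3.7 in Col-0 (log2 change 1.82, limma adjusted p = 0.0593).

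At stage 1.14, 896 probe sets passed (6.76%), 257 of them at least 2-fold, with 3087 at an unadjusted p under 0.05. Without the array that stood apart, SPH1 RNAi at stage 1.14 replicate 1, 690 passed, 454 higher and 236 lower, and 536 of them were among the 896. The count was 401, 447 and 376 without Col-0 at stage 1.14 replicates 1, 2 and 3, and 411 without SPH1 RNAi at stage 1.14 replicate 3. It was 154 with only the 6 arrays of this stage and 3345 with array quality weights. Leaving out the 2 repeated hybridisations leaves only replicate 1 of SPH1 RNAi at stage 1.14, the array that stood apart, so no count is given for that setting.

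The average of both stages is the mean of the genotype differences, so a large change at a single stage can pass. Of 1311 probe sets that passed, 901 were higher and 410 lower in SPH1 RNAi. In 557 (42.5%) of them the genotypes did not overlap at either stage and differed in the same direction. AT3G57950 was close to background in Col-0, at 1.57 ± 0.38 and 1.77 ± 0.45 (SD, n = 3), and rose to 43.7 ± 21.9 and 111 ± 27 in SPH1 RNAi (average log2 change 2.26 ± 0.17 SE, limma adjusted p = 2.97e-05). The AAA-type ATPase AT1G43910 rose 3.74-fold (adjusted p = 2.97e-05), and the lectin-like AT3G16530 fell 4.45-fold (adjusted p = 0.000901). A run of 29 measured neighbouring genes on chromosome 4 was 1.55-fold higher on average.

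Other higher genes in the average were AT1G21520 (1.95 ± 0.14) and the EF-hand protein AT3G47480 (1.83 ± 0.14), with AT5G55450 (1.74 ± 0.24), AT3G18250 (1.74 ± 0.30) and AT4G00700 (1.62 ± 0.20). The ankyrin repeat protein AT1G10340 (1.62 ± 0.16), the ATPases AT3G28510 (1.60 ± 0.21) and AT5G17760 (1.47 ± 0.11), the methionine sulfoxide reductase MSRB9 (1.60 ± 0.15) and AT1G13340 (1.55 ± 0.17) were also among the 12. Lower in the average were the thionin AT1G66100 (-1.59 ± 0.33), the methyltransferases of phosphocholine synthesis AT1G73600 (-1.34 ± 0.37) and PMEAMT (-0.86 ± 0.17), and the vacuolar invertase AT1G62660 (-0.94 ± 0.11). AT3G26960 (-1.16 ± 0.21), AT1G52510 (-1.15 ± 0.21), AT5G43150 (-0.98 ± 0.24), AT5G12050 (-0.97 ± 0.21), AT1G15260 (-0.94 ± 0.24), AT1G64370 (-0.90 ± 0.14) and GH9B8 (-0.88 ± 0.10) made up the rest. Adjusted p in limma ran from 2.97e-05 to 0.0395 in these 24, and by the rule for named genes the genotypes did not overlap at either stage. AT1G73600, AT1G15260 and AT5G43150 did not pass without replicate 2 of either genotype at stage 1.05, nor without Col-0 replicate 3 of that stage. AT1G73600 was also lost with any other single Col-0 array, or SPH1 RNAi array of stage 1.05, left out. AT1G15260 was also lost without Col-0 replicate 1 or SPH1 RNAi replicate 3 of stage 1.05, or Col-0 at stage 1.14 replicate 2 or 3.

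Flavonoid and anthocyanin synthesis was lower in the average as well: 3 of 4 genes fell and 1 did not pass, the same counts as adjusted over the list alone, with a median of -1.27 (camera adjusted p = 0.000425, and adjusted p = 0.216 with an estimated correlation). In the cold, drought and ABA list 1 of 4 fell, also over the list alone, with a median of -0.48 (camera adjusted p = 0.00858, and adjusted p = 0.216 with an estimated correlation). That median was -0.24 without SPH1 RNAi at stage 1.14 replicate 1, and also without Col-0 at stage 1.14 replicate 2. Photosystem subunits had a median of -0.27 and 0 of 4 genes past the threshold (camera adjusted p = 0.0261, and adjusted p = 0.351 with an estimated correlation); after quantile normalization the adjusted p was 0.232 and the median -0.18. The photosystem call was lost, with camera adjusted p from 0.0512 to 0.0798, without SPH1 RNAi at stage 1.14 replicate 1 or stage 1.05 replicate 2, or without Col-0 at stage 1.05 or 1.14 replicate 2. Expansins, heat shock and auxin response gave camera adjusted p from 0.945 to 0.946. PDF1.2 fell by 2.76, and GRX480 rose by 0.63.

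The run on chromosome 4 was singled out after the values had been seen. It was located on the stage 1.05 arrays alone and then measured at stage 1.14. From AT4G16800 to AT4G17486, in the gene order of TAIR10.1, lie 95 genes, 75 of them protein-coding, and 29 were measured. At stage 1.05 the mean log2 difference of SPH1 RNAi from Col-0 was 0.65 (SD 0.42 between genes), and at stage 1.14 it was 0.61 (SD 0.47). Of the 29 genes 28 were higher on average, 18 passed as higher and 0 as lower in limma. The average includes the stage 1.05 arrays that located the run. At stage 1.14 alone 27 were higher, 11 passed as higher and 0 as lower. AT4G16800 (1.30 ± 0.16 SE), AT4G17080 (1.19 ± 0.12), AT4G17486 (1.15 ± 0.15), AT4G17140 (1.06 ± 0.15) and AT4G17070 (1.02 ± 0.11) had the largest average differences, and EXLB1 (-0.16 ± 0.15) was the 1 gene below 0. The score of the run at stage 1.05 was 8.89, and the highest of 1000 shuffles of the gene order scored 3.87. At stage 1.14 its mean ranked 1 of 6815 runs of that length, and the next that did not overlap it had a mean of 0.29. The 12 measured genes before the run had a mean average difference of -0.02, and the 12 after it 0.11. Low values there at stage 1.05 follow from the search, which ends a run where the differences drop. Among these neighbours AT4G16660 (1.08), AT4G17670 (0.85) and AT4G17720 (0.43) passed as higher in the average. CSLA01 (-0.91) and AT4G16770 (-0.66) passed as lower. SPH1 lies on the same chromosome, with 72 genes between it and the run. Per array, the mean of the run lay between -0.43 and -0.21 in the 6 Col-0 arrays and between 0.15 and 0.41 in the 6 SPH1 RNAi arrays, relative to each gene's mean (exact permutation p = 0.1 at stage 1.14, the smallest possible).

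**Figure D3:**
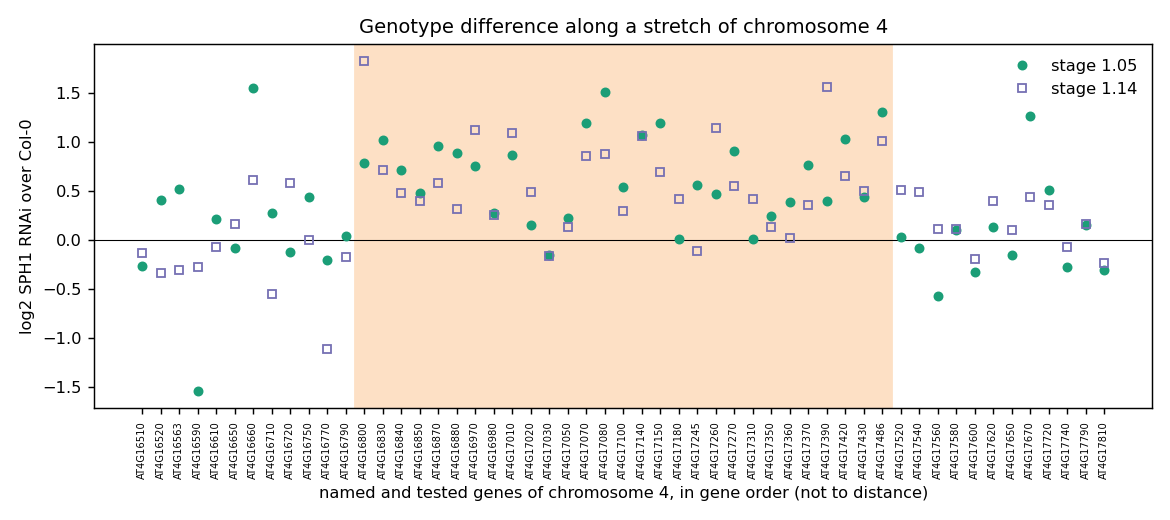
Log2 difference between SPH1 RNAi and Col-0 at both stages for the measured genes of a stretch of chromosome 4, in gene order and not to distance; the shaded part is the run of 29 genes. Inside it nearly all points lie above 0 at both stages, with means of 0.65 and 0.61.

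For the average, 1311 probe sets passed (9.88%), 177 of them at least 2-fold, with 3577 at an unadjusted p under 0.05. The calls at the separate stages shared 67 higher probe sets, where independent lists of these sizes would share 28.5, and 6 lower ones against 2.08. The count was 567 to 847 without any one of Col-0 at stage 1.05 replicate 3 (567) or 2 (803), SPH1 RNAi at stage 1.05 replicate 2 (643) or 3 (746), Col-0 at stage 1.14 replicate 3 (670) or 1 (778), or SPH1 RNAi at stage 1.14 replicate 3 (847). It was 811 with the actin ratio as a covariate and 3141 with array quality weights.

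The Col-0 stage comparison describes leaf development without the construct, and 5919 probe sets differed, 3139 higher and 2780 lower at stage 1.14. All 4 tested genes of the cold, drought and ABA list rose, COR47 by 3.17 on the log2 scale, from 131 ± 6 to 1320.2 ± 257 (SD, n = 3; limma adjusted p = 5.08e-07). CHI and AT1G13470, raised in young SPH1 RNAi rosettes, rose here 14.5-fold (adjusted p = 8.48e-06) and 14.8-fold (2.40e-07). The root marker PYK10 fell 14-fold, from 459 ± 115 to 17.3 ± 3.7 (adjusted p = 0.000125).

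Of the rising genes the largest change was in AT3G62550, with a log2 change of 5.12 ± 0.40 SE. It was followed by AT1G11210 (4.14 ± 0.21), AT1G56300 (4.10 ± 0.48), AT2G15960 (4.07 ± 0.57) and CCL (4.06 ± 0.59). The ERF-type transcription factor AT5G61590 (3.73 ± 0.37), AT2G39920 (3.70 ± 0.33), AT3G47160 (3.63 ± 0.41), the chloroplast cold-response protein COR15B (3.56 ± 0.30) and AT2G47890 (3.48 ± 0.31) also rose. The largest fall was in AT4G29030 (-4.30 ± 0.29), and its neighbour in gene order AT4G29020 fell too (-3.06 ± 0.41). AT1G60590 of the polygalacturonase family (-3.54 ± 0.35), the cysteine protease AT2G27420 (-3.44 ± 0.46), the GDSL-type lipase AT3G48460 (-3.19 ± 0.43) and AT1G23205 of the pectin methylesterase inhibitor family (-3.14 ± 0.33) fell. So did the lipid-transfer family members AT1G62500 (-3.14 ± 0.56), AT1G62510 (-3.05 ± 0.29) and AT4G22490 (-2.94 ± 0.50), the elongation factor AT5G12110 (-2.99 ± 0.67) and AT3G28220, a TRAF-like protein (-2.94 ± 0.14). Limma adjusted p was between 2.22e-07 and 0.00324 in these 24 genes.

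The median change of the cold, drought and ABA list between the Col-0 stages was 3.12, with 4 of 4 higher also over the list alone (camera adjusted p = 0.000383, and adjusted p = 0.144 with an estimated correlation). All 4 flavonoid and anthocyanin genes fell, also over the list alone, with a median of -1.80 (camera adjusted p = 0.0472, and adjusted p = 0.521 with an estimated correlation; 0.0645 after quantile normalization and 0.0553 with 1 in place of 16). With 1 array left out the flavonoid call held without Col-0 at stage 1.05 replicate 1 or stage 1.14 replicate 2, and was lost without each of the other 10 (adjusted p from 0.05 to 0.0996). The 3 tested cell division genes fell: PRL by 1.25, AUR2 by 1.21 and AUR1 by 0.97 (limma adjusted p from 0.000236 to 0.00134). Among expansins and xyloglucan endotransglucosylases EXPA15 (-1.21 ± 0.17) and XTH16 (-1.37 ± 0.37) fell and EXPA4 and EXPA8 did not pass (camera adjusted p = 0.212); over the list alone 3 fell and 1 rose. WRKY53 (1.65), SAG101 (1.13), GRX480 (0.91), the vacuolar processing enzyme GAMMA-VPE (2.99), the clock gene GI (2.04), the glucosinolate gene BCAT4 (1.25), the auxin-responsive IAA29 (1.89) and RR16 (0.92) rose, and SAG29 (-2.20), the leaf polarity regulator YAB3 (-0.64), ARR15 (-0.94) and the HSP70-binding protein Fes1A (-1.69) fell. Photosystem subunits had a median of -0.24, which became 0.09 after quantile normalization and -0.14 without Col-0 at stage 1.05 replicate 2, with 0 of 4 past the threshold (camera adjusted p = 0.336). Heat shock and auxin response had camera adjusted p of 0.173 and 0.310, and heat shock 0.0334 without Col-0 at stage 1.05 replicate 1. The Calvin cycle genes PRK (-0.48), RCA (-0.32) and SBPASE (-0.83) did not pass, nor did AGL24 (-0.81), a regulator of flowering.

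In the Col-0 stage comparison 44.6% of probe sets passed in limma, 2225 of them at least 2-fold. The stages also differed in the actin control ratio, given above. No left-out array or other setting moved the count by over 1.5 times, but after quantile normalization 2738 were higher and 2979 lower, so the balance of directions turned.

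The same comparison within SPH1 RNAi shows leaf development with the construct, and here 1358 probe sets differed, 767 higher and 591 lower at stage 1.14. AT1G11210 rose 13-fold, from 5.00 ± 0.95 to 271 ± 114 (SD, n = 3; limma adjusted p = 1.23e-06). COR15B rose 5.20-fold (adjusted p = 0.000692) and COR47 2.82-fold (adjusted p = 0.000481). AT3G28270 fell 13.6-fold, from 631 ± 163 to 41.0 ± 34.5 (adjusted p = 0.00941); without SPH1 RNAi at stage 1.14 replicate 1 the log2 change of AT3G28270 was -3.05 in place of -3.76.

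Also rising with stage in SPH1 RNAi were AT2G39920 (2.86 ± 0.33), AT2G15960 (2.75 ± 0.57), AT1G56300 (2.70 ± 0.48), AT3G62550 (2.58 ± 0.40), CCL (2.43 ± 0.59) and the osmotin OSM34 (2.46 ± 0.51). AT4G30650 (2.59 ± 0.21) and AT4G30660 (2.39 ± 0.26), small hydrophobic proteins of a cold- and salt-responsive family, rose as neighbours, with AT5G39520 (2.36 ± 0.38) and AT1G33055 (2.28 ± 0.65). AT1G33055 had a mean of 162 with an SD of 231 at stage 1.14, so its arrays differed widely. Without SPH1 RNAi at stage 1.14 replicate 1 the change was 1.17 in AT1G33055, 1.92 in AT2G15960 and -1.35 in AT1G13650, and CCL, AT1G55960 and CHIL did not pass. Without SPH1 RNAi at stage 1.14 replicate 2 it was 2.95 in AT1G33055, and CCL did not pass. Without SPH1 RNAi at stage 1.05 replicate 1 it was 1.47 in CCL, 1.89 in AT1G56300, -1.42 in AT1G55960 and -3.93 in AT5G12110, and AT2G15960, CHIL and AT2G27420 did not pass. AT1G33055 did not pass without 8 of the 12 arrays. AT5G12110 did not without replicate 2 or 3 of that group (-2.23 in AT5G12110 without the latter). Falling genes included AT5G12110 (-2.94 ± 0.67), AT3G28220 (-2.63 ± 0.14), the chalcone isomerase-like CHIL (-2.57 ± 0.65), AT1G60590 (-2.25 ± 0.35), AT5G57785 (-2.24 ± 0.14) and AT3G48460 (-2.23 ± 0.43). The thionin THI2.2 (-2.20 ± 0.27), AT1G55960 (-2.19 ± 0.52), AT2G27420 (-2.13 ± 0.46), AT1G13650 (-2.01 ± 0.43) and the jacalin-related lectin JAL22 (-1.98 ± 0.25) were the others. Adjusted p in limma lay between 1.01e-06 and 0.0433.

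In the cold, drought and ABA list 3 of 4 genes rose with stage in SPH1 RNAi, also over the list alone, and COR15A (0.56) did not pass; the median was 1.34 (camera adjusted p = 0.000288, and adjusted p = 0.134 with an estimated correlation). Photosystem subunits had a median of -0.54 with 0 of 4 past the threshold, while 4 fell adjusted over the list alone (camera adjusted p = 0.0123, and adjusted p = 0.279 with an estimated correlation; 0.620 and a median of -0.15 after quantile normalization). Without SPH1 RNAi at stage 1.14 replicate 1 the photosystem median was -0.34 (adjusted p = 0.0625). Heat shock had a median of -1.54 with 0 of 4 past it and 4 lower over the list alone (camera adjusted p = 0.00780, and adjusted p = 0.279 with an estimated correlation). That median was -1.01 with 64 and -2.01 with 1 in place of 16. It was -2.15 and -1.14 without SPH1 RNAi at stage 1.05 replicates 1 and 3. Flavonoid and anthocyanin synthesis had a median of -0.96 with 0 of 4 past it and 1 lower over the list alone (camera adjusted p = 0.0344, and adjusted p = 0.375 with an estimated correlation; 0.0554 after quantile normalization). The flavonoid call was also lost with 64 in place of 16 (adjusted p = 0.0714, median -0.45) and without replicate 1 of SPH1 RNAi at stage 1.05 (0.0590) or 1.14 (0.0887). Expansins and auxin response gave camera adjusted p of 0.522 and 0.837. WRKY53 (1.07), GAMMA-VPE (1.81) and GI (1.77) rose, LHCB4.2 fell by 0.62, and PYK10 fell by 1.79 (limma adjusted p = 0.0487). The cell division genes PRL (-0.22), AUR2 (-0.37) and AUR1 (-0.09) did not pass, nor did GRX480 (0.17), SAG29 (0.39) or the 3 Calvin cycle genes.

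Between the SPH1 RNAi stages 10.2% of probe sets passed in limma, 467 of them at least 2-fold. The count was 669 without SPH1 RNAi at stage 1.05 replicate 1 and 762 without its replicate 3, and 1082 without SPH1 RNAi at stage 1.14 replicate 1. It was 259 with the actin ratio as a covariate and 462 with only these 6 arrays.

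The interaction asks whether the difference between the genotypes differs between the stages, and 446 probe sets passed, 196 positive and 250 negative. The RING-finger ubiquitin ligase RING1, known from programmed cell death, was 206 ± 39 in Col-0 and 1133 ± 74 in SPH1 RNAi at stage 1.05, and 1433 ± 305 and 1642 ± 198 at stage 1.14 (SD, n = 3; interaction log2 -2.18 ± 0.26 SE, limma adjusted p = 0.00318). CHI had the same shape (-3.48, adjusted p = 0.00619). AT4G29030 lay at 775 ± 41 and 701 ± 119 at stage 1.05, and at 24.6 ± 7.1 in Col-0 and 400.2 ± 190.3 in SPH1 RNAi at stage 1.14 (3.41 ± 0.41, adjusted p = 0.00314).

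The 10 genes with the smallest p in the interaction were led by AT1G13470 (-3.39 ± 0.28, limma adjusted p = 0.000435). AT1G76960 (-3.68 ± 0.47), the phospholipid-transporting ATPase AT3G25610 (-1.82 ± 0.24), the calcium-binding EF-hand protein AT3G25600 (-1.74 ± 0.25) and AT1G67920 (-1.59 ± 0.23) were negative, each higher in SPH1 RNAi at stage 1.05. AT1G10640 of the polygalacturonase family (1.68 ± 0.20), AT3G13230, an RNA-binding protein (1.38 ± 0.19), and the ribosomal protein gene AT1G07070 (1.15 ± 0.17) were positive, each higher in SPH1 RNAi at stage 1.14. In AT1G07070 the genotypes differed both ways, by -0.48 at stage 1.05 (limma adjusted p = 0.0324) and by 0.67 at stage 1.14 (adjusted p = 0.00829). In the cold, drought and ABA list COR47 (-1.67) and LTI30 (-1.17) passed as negative, all 4 did so adjusted over the list alone, and the median was -1.42 (camera adjusted p = 0.000189, and adjusted p = 0.120 with an estimated correlation). SAG29 was positive (2.59, limma adjusted p = 0.0425). The 5 other lists that camera tested gave adjusted p from 0.209 to 0.769. Auxin response was called lower without SPH1 RNAi at stage 1.14 replicate 1 (0.0273), and flavonoid synthesis, at 0.209, was called higher without Col-0 at stage 1.14 replicate 2 (2.94e-06). The 3 cell division genes, with 0.84, 1.03 and 0.88, did not pass but were all positive adjusted over the list alone.

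Across the 13263 probe sets, the stage change in SPH1 RNAi was 51.4% of that in Col-0 by the noise-corrected slope of 0.51. The slope was 0.46 to 0.55 with each array left out, and its jackknife SE over the arrays was 0.083. The correlation of the stage changes was 0.79 across probe sets, which are not independent replicates. Of the probe sets higher at stage 1.14 in SPH1 RNAi, 700 of 767 were higher in Col-0 too, where independent lists would share 182, and 536 of 591 lower ones were lower in both, against 124. The spread of the stage changes was 0.79 in Col-0 and 0.43 in SPH1 RNAi (SD of log2 change, corrected for error). The correlation above was not corrected in this way.

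**Figure D4:**
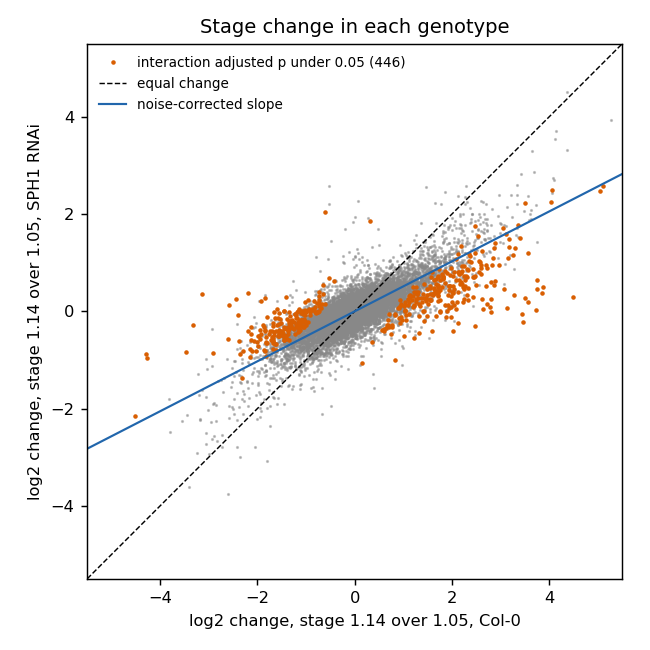
Log2 change from stage 1.05 to 1.14 in SPH1 RNAi (vertical) against that in Col-0 (horizontal) for each tested probe set, with the 446 that passed the interaction in orange. The noise-corrected slope of 0.51 lies below the line of equal change.

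For the interaction 3.36% of probe sets passed in limma, 332 of them with a log2 value of at least 1 in size, and 2632 had an unadjusted p under 0.05. The count was 119 and 159 without Col-0 at stage 1.05 replicates 2 and 3, 131 and 169 without SPH1 RNAi at stage 1.05 replicates 2 and 3, 705 without its replicate 1, 211 and 171 without Col-0 at stage 1.14 replicates 1 and 3, and 230 without SPH1 RNAi at stage 1.14 replicate 3. It was 236 with no filter on the mean and 2137 with array quality weights. Without SPH1 RNAi at stage 1.14 replicate 2 it was 452, with 254 positive and 198 negative, so the balance turned there.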

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

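The tests of the narrower stage difference in SPH1 RNAi were chosen after that pattern had been seen; the interaction test was set before. Named genes and members of the gene lists fixed beforehand are given here where the difference between SPH1 RNAi and Col-0 differed between the stages in limma's interaction test, with adjusted p from 0.000435 to 0.0425. A negative interaction log2 value means that the genotype difference was more negative, or less positive, at stage 1.14 than at stage 1.05.

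Negative values were found in AT1G76960 (-3.68), AT2G44240 (-3.49), CHI (-3.48), AT1G13470 (-3.39), AT3G62550 (-2.54), RING1 (-2.18), AT3G28540 (-2.04), AT3G25610 (-1.82), AT1G30250 (-1.81), AT4G00700 (-1.74) and AT3G25600 (-1.74). They were also found in AT1G78460 (-1.71), AT1G10340 (-1.71), COR47 (-1.67), AT1G21520 (-1.67), AT3G47480 (-1.62), AT1G67920 (-1.59), AT5G62360 (-1.52), AT3G16800 (-1.31) and LTI30 (-1.17). Positive values were found in AT1G62500 (3.49), AT4G29030 (3.41), AT2G28790 (2.72), GH9B13 (2.69), SAG29 (2.59), AT5G45670 (2.04), AT1G10640 (1.68), AT4G02850 (1.49), AT3G44970 (1.38), AT3G13230 (1.38), GH9C2 (1.18) and AT1G07070 (1.15).

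The pattern behind these values is a narrower stage difference in SPH1 RNAi, with a slope of 0.51 on the Col-0 stage change. A single array out of place and normalization are argued against as the whole cause. The slope was 0.47 without SPH1 RNAi at stage 1.14 replicate 1 and 0.53 after quantile normalization, far from 1 each time. A wrong label of the array without the RNAi tag is argued against too: its mean over the chromosome 4 run was 0.40, above all 6 Col-0 arrays, which reached -0.21 at most. With the actin ratio as a covariate the slope was 0.50, but this test cannot decide on RNA degradation. The ratio changed between the stages by -0.87 in Col-0 and -0.83 in SPH1 RNAi, so the covariate took nearly the same amount off both stage changes. The narrowing can be split between the stages. The genotype difference at stage 1.05 covaried with the Col-0 stage change by 0.188 more than shared Col-0 arrays add (0.211 observed, 0.0230 simulated, and 0.191 when both differences used different Col-0 arrays). This places young SPH1 RNAi rosettes toward the older profile by 30.3% of the Col-0 change. At stage 1.14 a further 19.8% was missing, which places older SPH1 RNAi rosettes toward the younger profile. These shares restate the slope and are no separate evidence for a cause. Whether the narrower stage difference reflects the construct, a difference in the age or conditions of the plants sampled, or a second change in the RNAi line was not tested and stays open.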

How the results depend on the processing

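The actin covariate, and for the gene lists each array left out and 1 or 64 in place of 16, were chosen after the results were seen; the other alternatives were set before. For the 6 comparisons, counts stayed within 1.5 times under quantile normalization, 1 or 64 in place of 16 before the log2, a minimum mean of 64 and no intensity trend. With array quality weights the count was 1753 against 707 for SPH1 RNAi against Col-0 at stage 1.05, 3345 against 896 at stage 1.14, 3141 against 1311 for the average and 2137 against 446 for the interaction; these weights ranged from 0.257 for SPH1 RNAi at stage 1.14 replicate 1 to 6.04 for Col-0 at stage 1.14 replicate 3. Without the 2 repeated hybridisations it was 1762 at stage 1.14, 2353 for the average, 2152 for the SPH1 RNAi stage change and 856 for the interaction, and the 1 array left in that group was assumed to vary like the others. With only the 6 arrays of the groups compared it was 154 at stage 1.14 and 462 for the SPH1 RNAi stage change, but 781 at stage 1.05 and 6403 for the Col-0 stage change. The actin covariate gave 811 for the average and 259 for the SPH1 RNAi stage change, and no filter on the mean gave 236 for the interaction. The cause was not tested.

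Leaving out each array in turn gave 365 to 1060 at stage 1.05, 376 to 1102 at stage 1.14, 567 to 1641 for the average, 4665 to 6439 for the Col-0 stage change, 669 to 1501 for the SPH1 RNAi stage change and 119 to 705 for the interaction. With the replicate number as a block the counts were 731, 998, 1345, 5941, 1362 and 523 in the same order, and no call of the 6 tested lists fixed beforehand changed; the 4 added lists were not run with the block. Whether the numbers pair the arrays is not settled by these values. The correlation of deviations was over 0.1 in 7 of 18 pairs with the same number (-0.25 to 0.49). Between the genotypes at stage 1.14 it was 0.49 and 0.36 in replicates 1 and 2, but -0.25 in replicate 3. In 5 of 12 arrays the best correlation was with an array of their own number.

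No named gene changed sign under any alternative. Of 130 values named across the comparisons, 96 stayed past the threshold in each setting in which they were tested. The other 34 lost it at least once, 14 of them at stage 1.14 and 12 in the SPH1 RNAi stage change. Not all were tested in each setting, as with a minimum mean of 64, where 119 were. For the 6 tested lists fixed beforehand, 14 of 36 tests were called; all 14 calls were lost with an estimated correlation, and 6 with quantile normalization, which were flavonoid and photosystem calls. Signal over background limits what could be tested: 54.0% to 59.8% of probe sets on an array reached 32.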

Other observations

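The lists of ribosomal and receptor genes, and the tests of the chromosome 4 run, were chosen after the results were seen; the splits of the arrays were set before. Genes for cytosolic ribosomal proteins, 120 of 227 in the list tested, fell with stage in Col-0 and were higher in older leaves of SPH1 RNAi. In Col-0, 113 fell from stage 1.05 to 1.14 and 0 rose, with a median log2 change of -1.30 (camera adjusted p = 2.36e-39, and adjusted p = 0.0550 with an estimated correlation; 0.0306 without Col-0 at stage 1.14 replicate 2). In SPH1 RNAi, 33 fell and 1 rose, with a median of -0.47, or -0.27 after quantile normalization (camera adjusted p = 1.77e-24, and adjusted p = 0.138 with an estimated correlation). At stage 1.14, 82 were higher in SPH1 RNAi than in Col-0 and 0 lower, with a median of 0.71 (camera adjusted p = 3.55e-45, and adjusted p = 0.0807 with an estimated correlation; 0.0465 after quantile normalization). At stage 1.05 the median was -0.10, with 1 higher and 1 lower (camera adjusted p = 0.000139, and adjusted p = 0.607 with an estimated correlation), and after quantile normalization the call was lost (median -0.002, adjusted p = 0.919). In the average, 30 were higher in SPH1 RNAi and 0 lower (median 0.32, camera adjusted p = 1.08e-16, and adjusted p = 0.250 with an estimated correlation). The interaction was positive in 40 and negative in 0, with a median of 0.83 (camera adjusted p = 1.79e-45, and adjusted p = 0.0397 with an estimated correlation). That median was 0.83 after quantile normalization and 0.71 without SPH1 RNAi at stage 1.14 replicate 1, where the call with an estimated correlation was lost (adjusted p = 0.0721). With 1 array left out that call held only without a Col-0 array of stage 1.14, and for the other 9 the adjusted p was 0.0535 to 0.0975. The root marker PYK10 had log2 changes of -3.81 between the stages in Col-0, -1.79 in SPH1 RNAi and 1.82 between the genotypes at stage 1.14, with an interaction of 2.02 (limma adjusted p = 0.155). The actin control ratio in Col-0 was 1.88 at stage 1.05 and 1.01 at stage 1.14.

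Genes for immune receptors with TIR or NB-LRR domains, 33 of 102 tested, differed between the genotypes in young leaves. At stage 1.05, 8 were higher in SPH1 RNAi and 0 lower, with a median of 0.47 (camera adjusted p = 6.18e-08, and adjusted p = 0.00572 with an estimated correlation). CSA1 (0.88 ± 0.19 SE), AT5G51630 (0.85 ± 0.17), AT1G63880 (0.83 ± 0.21) and AT4G12010 (0.81 ± 0.13) were among the 8. At stage 1.14, 2 were higher and 1 lower, with a median of 0.11 (camera adjusted p = 0.395, and 0.621 with an estimated correlation). In Col-0, 18 rose with stage and 0 fell (median 0.50, camera adjusted p = 6.89e-05, and adjusted p = 0.0332 with an estimated correlation). The call with an estimated correlation was lost without SPH1 RNAi at stage 1.05 replicate 1 (0.0650), SPH1 RNAi at stage 1.14 replicate 2 (0.0663) or Col-0 at stage 1.05 replicate 2 (0.0515). In SPH1 RNAi, 2 rose with stage and 0 fell (median 0.26, camera adjusted p = 0.00561, and adjusted p = 0.138 with an estimated correlation; median 0.16 and camera adjusted p = 0.0523 without SPH1 RNAi at stage 1.14 replicate 3). In the average, 9 were higher in SPH1 RNAi and 0 lower (median 0.28, camera adjusted p = 0.000101, and adjusted p = 0.0417 with an estimated correlation). That last call was lost after quantile normalization (0.0552), and with 1 array left out it held only without SPH1 RNAi at stage 1.14 replicates 1 or 3 or stage 1.05 replicate 2, or Col-0 at stage 1.14 replicate 2 (0.0503 to 0.127 for the other 8). The interaction had a median of -0.39, with 1 of 33 past the threshold (camera adjusted p = 0.000394, and adjusted p = 0.0397 with an estimated correlation). Without SPH1 RNAi at stage 1.14 replicate 1 the interaction call with an estimated correlation was lost (adjusted p = 0.0721), and it held only without Col-0 at stage 1.14 replicates 1 or 3 or SPH1 RNAi at stage 1.14 replicate 3 (0.0539 to 0.0975 for the other 9). These medians kept their sign under quantile normalization and with 1 or 64 in place of 16 before the log2. The one at stage 1.14 was 0.02 after quantile normalization. With 64 they were 0.26 at stage 1.05, 0.07 at stage 1.14, 0.13 in the average, 0.31 in Col-0, 0.14 in SPH1 RNAi and -0.18 for the interaction. The 69 plastid-encoded genes were called lower by camera at stage 1.05 (median -0.23, adjusted p = 0.000139), stage 1.14 (-0.12, 0.00787), in the average (-0.20, 1.68e-05) and with stage in Col-0 (-0.22, 0.00811; 8 fell) and SPH1 RNAi (-0.29, 0.00130; 3 fell). All 5 calls were lost after quantile normalization (adjusted p from 0.184 to 0.955) and with an estimated correlation (0.492 to 0.772), and 4 of them also with 1 array left out: at stage 1.05 (0.759 without SPH1 RNAi and 0.211 without Col-0 replicate 2 of that stage), at stage 1.14 (0.0948 without SPH1 RNAi replicate 2), in Col-0 (0.137 without stage 1.05 replicate 2) and in SPH1 RNAi (0.821 without stage 1.05 replicate 1). For the interaction, at 0.507, the list was called higher without SPH1 RNAi at stage 1.05 replicate 1 (0.000634) and lower without its replicate 2 (0.00567). The 10 tested mitochondria-encoded genes were not called (camera adjusted p from 0.114 to 0.778), but at stage 1.14 they were without SPH1 RNAi at stage 1.14 replicate 2 (0.0346), and with stage in SPH1 RNAi without that array (0.00787) or SPH1 RNAi at stage 1.05 replicate 1 (0.0472).

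The run of 29 measured genes on chromosome 4 was higher in all 6 SPH1 RNAi arrays than in all 6 Col-0 arrays. A response that fades with stage is argued against, since the run's genotype difference shrank by 0.044 (SE 0.05 over arrays) from stage 1.05 to 1.14, far from the 0.33 that a loss of 50% would need. Scaling is argued against, with a mean of 0.58 after quantile normalization. Signal shared between related receptor genes could not be decided by a count of such genes. Of the 29 measured genes, 0 are in the receptor list and 0 have a probe set marked as shared. But only 33 and 34 of the 6955 genes put in order do, so most runs of this length would hold 0. Probe sets listed with several genes were left out of the order beforehand. Only 29 of the 95 genes in the stretch were measured, so receptor genes among the others are not covered. A candidate explanation is a local change of the chromosome in the RNAi plants, such as an extra copy, since the run found at stage 1.05 ranked 1 of 6815 at stage 1.14. Whether a copy was gained, whether the Col-0 plants carry the difference instead, and whether the construct or a linked variant is behind it were not tested and stay open.

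For the average effect, 1 of 100 splits of the arrays within the stages, the real one, gave as many probe sets as 1311. The highest other gave 539. This share is under 0.05, which argues against chance. For the interaction, the additive effects of genotype and stage were taken off before the 12 arrays were put into other groups. Here 2 of 100 reassignments gave as many as the real 446, the real one included. The share is under 0.05, but the highest other gave 490, more than the real grouping, so chance is not excluded. The comparisons of 3 arrays with 3 have 10 splits each, too few for a share under 0.05, and in each 1 of 10 gave as many as the real split. The real count and the highest other were 707 and 2 at stage 1.05, 896 and 274 at stage 1.14, 5919 and 0 for the Col-0 stage change, and 1358 and 0 for the SPH1 RNAi stage change.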
